A study of Homo sapiens with 6 samples.

How the data were processed

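Expression was profiled in 6 cultures of MDA-MB-231 cells with 1 array each, 3 grown in 25 mM glucose and 3 in 10 mM fructose. Per the labels' protocols, cells were adapted for 25 days, total RNA was taken on silica columns with DNase digestion on the column, and labelled with biotin. Replicates are separately adapted batches of cells, per the series' design text. The deposited table holds 1 intensity per probe set and array, made with RMA per the submitters' processing notes. RMA corrects the background, normalizes between arrays and summarises probes into a probe set. Its version, the program that ran it, and any genome build or filter on probe sets are not given in the sources used here. RMA usually yields log2 values, but the deposited intensities were all above 0 and reached 9287, so they were read as being on the linear scale and log2 was taken before every test. No pseudocount was needed and the authors' normalization was kept. Array data carry no read depth, and the number of arrays limits the precision.

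The table had 32321 rows. Of these, 4091 had identifiers below the lowest identifier paired with a gene and were taken to be control probe sets, which is a reading of the numbering and not a statement of the labels. They were left out, and 28230 probe sets were tested. Gene names came from the platform annotation of the array. It paired 19158 tested probe sets with 1 gene and 1388 with several, and 7684 are unnamed here. Gene numbers of 19128 of the 19158 matched a current gene table, and 0 symbols needed an update. A gene was represented by its probe set with the highest mean log2 value among those with 1 symbol, which gave 18404 genes, 637 of them with more than 1 probe set. For the named genes with a further probe set, ATF4, EPCAM, ZEB2 and MTHFD2, that probe set had the same direction. No coordinates are given, because the build behind the annotation is not given in the sources used here.

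The groups were compared as fructose minus glucose with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided, no covariate), with Benjamini-Hochberg adjustment over the 28230 probe sets and a threshold of 0.05. The 2-fold count also needed an absolute log2 difference of at least 1. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, on the representative probe sets, with adjustment over 24 lists. Those lists held 496 members, of which 450 were measured and the rest were not analysed here. Camera with an estimated correlation and fry, a rotation test of a list's own shift, were run beside it. A further 3 lists held markers of luminal breast cells, leukocytes and fibroblasts and were adjusted among themselves. The groups, tests, lists and all settings but those named as later additions were fixed before the data were examined.

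Named genes followed a rule. It took the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, or all of them if fewer, provided that the arrays of each sugar did not overlap and the brighter group mean was above the median probe set. It also took up to 4 members of each list with the smallest p, and TXNIP, ARRDC4, SLC2A1, SLC2A3, SLC2A5, KHK, HK2, PFKP, LDHA, PDK1, IL6, CXCL8 and MKI67 in every case. Genes outside this rule are said to be chosen after their values were seen, or are given as members of a marker list.

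The alternatives were a replicate block, each array left out in turn, quantile normalization again, centring each array on its median, bright probe sets alone, an intensity trend with robust variances, array weights, the mean of a gene's probe sets, representative probe sets alone, an unmoderated test of the same model, the estimated correlation and fry. Keeping the control probe sets and leaving TXNIP out of its list were added later. All 10 splits of the 6 arrays into 3 and 3 were refitted. Procedures were first tested on simulated data, with 10 tables of 28230 probe sets at the variances of these arrays and 200 probe sets changed in each. The test recovered 44.5% of 1.5-fold, 88.5% of 2-fold and 98.5% of 4-fold changes, with 0 wrong signs and 74 false calls over all tables. The changed probe sets were spread about evenly over these 3 sizes, and many large changes ease the adjusted threshold. Recovery in a table with few large changes was not tested, so these rates need not hold for the real arrays. Of the simulated lists, 40 of 40 shifted by 0.2 were called and 0 of 200 lists without a shift. The simulated genes varied independently of each other, so these counts do not show how often lists of correlated genes are called without a shift.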

Results

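Gene expression was measured in MDA-MB-231 cells, an established human line from a triple-negative breast cancer, after growth on 1 of 2 sugars. Glucose was supplied at 25 mM and fructose at 10 mM, and the cells were passaged in these media for 25 days. The kind of sugar, its concentration and the absence of glucose differed together, so their effects cannot be told apart here. Each group had 3 arrays, and each array held total RNA from a separately adapted batch of cells, taken at about 70% confluency and about 24 hours after fresh medium. Fructose is taken up and broken down more slowly than glucose by most cultured cells, and the title of the series frames the comparison as the effect of restricted glycolysis on gene expression. The RMA intensities of the 6 arrays ran from 2.15 to 9287, with medians between 33.1 and 34.8. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.095. In a principal component analysis the first component held 28.8% of the variance and parted the glucose arrays, at -13.5, -14.6 and -14.8, from the fructose arrays, at 17.9, 5.67 and 19.3. Fructose replicate 2 therefore lay nearest to the glucose arrays, and it also lay apart from the others on the next component (20.6%). Arrays of the same sugar differed with an SD of 0.225 to 0.260 over probe sets (log2), and arrays of different sugars with 0.251 to 0.273, so no pair of arrays was a copy of the other.

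The largest difference between the sugars was in TXNIP, the thioredoxin-interacting protein that restrains glucose uptake and is transcribed in response to glucose. Its level in fructose was 14.0-fold lower. It was the single gene that passed the test over all 28230 probe sets. Among 24 gene lists, 15 were shifted as groups by small amounts with camera, and none with an estimated correlation, where the smallest adjusted p was 0.35. Genes of cholesterol synthesis, the ATF4 stress response, the unfolded protein response, NF-kB and the lysosome were higher in fructose, and genes of DNA replication, cell division and histones were lower. By fry, which asks only whether a list moves on balance in a single direction, 8 of the 15 passed, and the adjusted p was 0.19 for the ATF4 list, 0.29 for the unfolded protein response, 0.10 for NF-kB, 0.13 each for DNA replication, cell division and fatty acid oxidation and 0.11 for histones. The glycolytic enzymes and the respiratory chain were not shifted past the threshold. Fry's mixed test, which counts differences in either direction, passed 20 of the 24 lists. Its adjusted p was 0.017 for the glycolytic enzymes, 4.82e-04 for the citric acid cycle list and 0.098 for the respiratory chain. A list without a shift here can therefore still hold members that differ in opposite directions.

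TXNIP (probe set 7904726) had an intensity of 1692 ± 77.4 (SD, n = 3) in glucose and 122 ± 14.3 (SD, n = 3) in fructose. In glucose it was brighter than 98.7% of the tested probe sets, and in fructose than 75.2%. Its log2 value fell by 3.80 (SE 0.10, 95% interval -4.04 to -3.57, limma adjusted p = 4.70e-05), and each fructose array lay below each glucose array. The other 6 measured members of the MondoA and ChREBP list, whose transcription factors respond to hexose phosphates, did not pass over all probe sets. As a group the 7 genes fell (camera adjusted p = 0.011), with a median of -0.18 and 5 of 7 lower in fructose. The adjusted p was 0.35 with an estimated correlation. When adjusted over the list alone, 3 genes fell and 1 rose. ARRDC4, a glucose-responsive paralog of TXNIP, differed by -0.67 (SE 0.19) from a dim mean of 4.41 in glucose, and KLF10 by -0.33. BHLHE40, a circadian repressor, was higher by 0.37. The shift of this list rested on TXNIP, since without that gene its adjusted p was 0.32. It also missed the threshold without fructose replicate 2 (0.052), and its median was -0.07 without that array, -0.31 without fructose replicate 1 and -0.10 without glucose replicate 2.

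**Figure D1:**
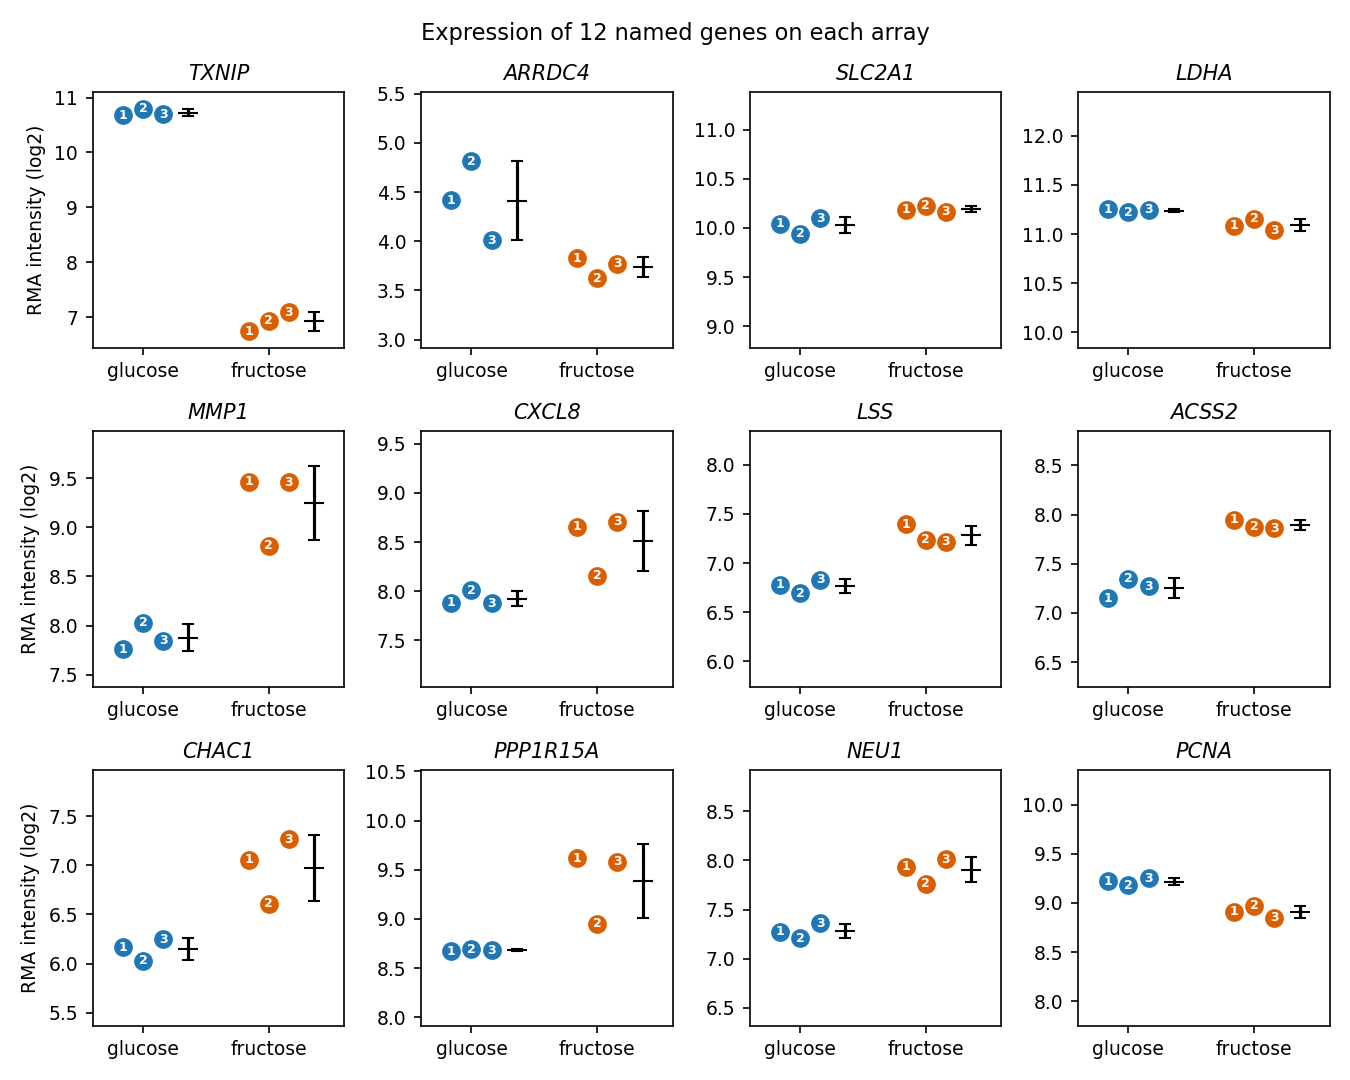
Log2 RMA intensity of 12 named genes on each array, with glucose in blue and fructose in orange. Points carry their replicate number, bars give the mean and SD of 3 arrays, and axis ranges differ between panels, where TXNIP drops from a mean of 10.72 to 6.92 and MMP1, CHAC1 and PPP1R15A lie lower in fructose replicate 2 than in the other fructose arrays.

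The 16 measured glycolytic enzymes did not shift (adjusted p = 0.42), with a median of -0.02 and 10 of 16 lower in fructose. That median was -0.04 without glucose replicate 1 and 0.01 without glucose replicate 3. None of them passed, whether over all probe sets or adjusted over the list alone. PGK1, an ATP-forming enzyme of lower glycolysis, differed by -0.18, LDHA, which makes lactate, by -0.15 (95% interval -0.30 to 0.01), HK2, which phosphorylates hexoses, by 0.19 and PFKP by 0.11. The list of sugar and lactate transport and fructose metabolism was not shifted either (adjusted p = 0.60). Its single member past the threshold when adjusted over the list alone was the glucose transporter SLC2A3, higher by 0.41. SLC2A1, the main glucose transporter of most cell lines, was higher by 0.16 and SLC2A12 differed by -0.38. SLC2A5, the fructose transporter, and KHK, which phosphorylates fructose, were both dim. SLC2A5 had a mean log2 of 4.21 in glucose and differed by 0.04 (95% interval -0.13 to 0.20), and KHK had 4.86 and differed by -0.16 (95% interval -0.47 to 0.14), where the median of all tested probe sets was 5.01.

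The 7 measured genes of the pentose phosphate pathway were not shifted as a group (adjusted p = 0.29), although 4 rose and 1 fell when adjusted over the list alone. Its median was 0.20, with 0.18, 0.21 and 0.20 on the fructose arrays, and lay at percentile 99.8 of random lists matched on mean expression. PGLS (0.40), TALDO1 (0.37) and TKT (0.27) were higher in fructose, and RPE was lower with -0.31. In the hexosamine pathway (6 genes, adjusted p = 0.75), OGA, which removes O-linked N-acetylglucosamine from proteins, differed by -0.49 and NAGK by 0.26. These were the 2 members past the threshold when adjusted over the list alone. The test gave the hexosamine list a downward sign while its median was 0.02, and between 0.0018 and 0.040 with an array left out. Serine and one-carbon metabolism (10 genes) had an adjusted p of 0.55, with SHMT2 at 0.25 and PSAT1 at 0.28. None of its members passed when adjusted over the list alone. The lists of pyruvate dehydrogenase with the citric acid cycle (21 genes) and of oxidative phosphorylation (47 genes) both had adjusted p values of 0.89 and no member past the threshold when adjusted over the list alone. Their median differences were -0.0018 and 0.011. The members with the smallest p were SUCLG2 (0.35), IDH3G (0.25) and DLD (-0.21) in the first and UQCRC1 (0.21), COX5B (0.18) and UQCRB (-0.36) in the second. For the citric acid cycle and for oxidative phosphorylation the sign of the median and that of the test were opposite, but the median changed sign in 3 and in 1, respectively, of the 6 fits that left out an array.

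Genes of cholesterol synthesis and uptake, the targets of SREBP2, rose as a group (adjusted p = 1.10e-06), and all 18 measured members were higher in fructose. The median was 0.19, and the adjusted p was 0.35 with an estimated correlation. Of the 18, 8 rose and 10 did not pass when adjusted over the list alone. LSS, which closes the sterol ring, was higher by 0.51 (SE 0.08), MVK by 0.43, DHCR7 by 0.41 and HMGCS1, an early enzyme of the pathway, by 0.30. Fatty acid synthesis genes, the targets of SREBP1, also rose (13 genes, 11 higher, adjusted p = 0.0091 and 0.36 with an estimated correlation). Their median was 0.07, and 0.11 without glucose replicate 3. The 4 that rose when adjusted over the list alone were ACSS2, which makes acetyl-CoA from acetate (0.64, SE 0.08), FASN (0.41), LPIN1 (0.33) and ACLY (0.26). Genes of fatty acid oxidation and PPAR targets fell as a group (18 genes, 13 lower, adjusted p = 0.011 and 0.36 with an estimated correlation). The median was -0.09, with -0.10, 0.00 and -0.14 on the fructose arrays, and 2 fell when adjusted over the list alone. PDK4, a kinase that blocks pyruvate dehydrogenase and was dim (4.69 in glucose), differed by -0.37, SLC25A20 by -0.42 and ACAA2 by -0.33, whereas PPARA was higher by 0.35. Without fructose replicate 3 the adjusted p of this list was 0.14, and without fructose replicate 1 its median was -0.04.

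The integrated stress response list, led by the transcription factor ATF4, rose by a median of 0.28 (24 genes, 21 higher, adjusted p = 2.31e-05 and 0.45 with an estimated correlation). Among its genes 5 rose when adjusted over the list alone. CHAC1, which degrades glutathione, was higher by 0.83 (SE 0.16), PPP1R15A, which restores translation after stress, by 0.70 (SE 0.17), and ATF4 and the amino acid transporter SLC7A5 by 0.28 each. The list of endoplasmic reticulum chaperones and unfolded protein response genes rose as a group (19 genes, 17 higher, adjusted p = 0.0022 and 0.57 with an estimated correlation), and none passed when adjusted over the list alone. XBP1 was higher by 0.36, SEC24D by 0.35, CRELD2 by 0.31 and EDEM1 by 0.27. Several major chaperones and folding factors of the list, chosen after their values were seen, lay near 0, with HSPA5 at 0.03, PDIA6 at 0.03, DNAJB11 at 0.01, HSP90B1 at -0.01 and DNAJC3 at -0.06. Both lists stood higher on 2 of the 3 fructose arrays. The median difference of the ATF4 list from the glucose mean was 0.41 and 0.40 on fructose replicates 1 and 3 and -0.01 on replicate 2, and that of the unfolded protein response list was 0.31, 0.30 and -0.07. The median of the latter list, 0.19 over all arrays, was 0.32 without fructose replicate 2 and 0.13 without fructose replicate 1. NRF2 targets, which answer oxidative stress, rose as well (17 genes, 13 higher, median 0.14, adjusted p = 0.012 and 0.35 with an estimated correlation), with 0.21, 0.05 and 0.17 on the fructose arrays. Here 2 rose when adjusted over the list alone, the aldo-keto reductase AKR1C3 (0.54) and the ferritin light chain FTL (0.27). SLC48A1 was higher by 0.24 and NQO1 by 0.23.

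**Figure D2:**
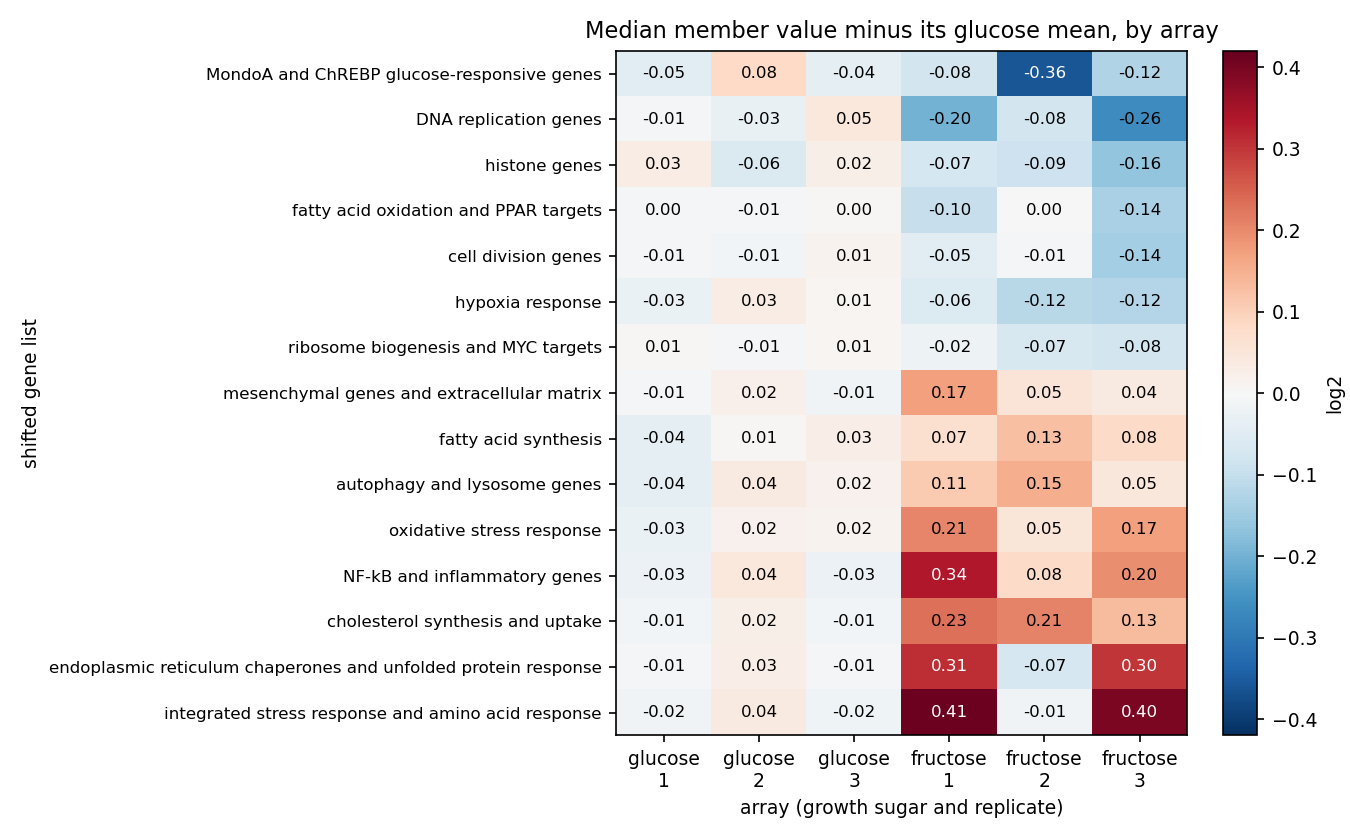
Median over the measured members of each of the 15 shifted lists, as the log2 value on an array minus the mean of the 3 glucose arrays, with red above and blue below that mean. The ATF4 list reads 0.41, -0.01 and 0.40 on the fructose arrays, and cholesterol synthesis 0.23, 0.21 and 0.13.

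Autophagy and lysosome genes rose as a group (23 genes, 17 higher, median 0.09, adjusted p = 0.0018 and 0.36 with an estimated correlation). Adjusted over the list alone, 6 rose. The sialidase NEU1 was higher by 0.62 (SE 0.09), the autophagy receptor SQSTM1 by 0.54, the protease CTSD by 0.50 and the lysosomal cholesterol exporter NPC1 by 0.43. NF-kB and inflammatory genes rose too (27 genes, 20 higher, median 0.18, adjusted p = 4.41e-04 and 0.36 with an estimated correlation), with 6 up when adjusted over the list alone. The median was 0.11 without glucose replicate 3, and on the fructose arrays it was 0.34, 0.08 and 0.20. The collagenase MMP1 was higher by 1.37 (SE 0.18, 2.58-fold, adjusted p = 0.13 over all probe sets). TNFAIP3, a brake on NF-kB with a dim mean of 4.28 in glucose, was higher by 0.48, RELB by 0.45, CXCL1 by 0.45 and the neutrophil chemokine CXCL8 by 0.58. IL6 was higher by 0.18 (95% interval -0.30 to 0.66). The interferon response list was not shifted (25 genes, adjusted p = 0.52), and none of its members passed when adjusted over the list alone. Its test pointed down, and its median of 0.0035 turned negative in 3 of the 6 fits that left out an array. IFIT2 differed by -0.46, IFIT1 by -0.43, OAS2 by 0.39 and XAF1 by 0.23.

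DNA replication genes fell as a group by a median of 0.15 (24 genes, 20 lower, adjusted p = 7.36e-07 and 0.38 with an estimated correlation). The 2 that fell when adjusted over the list alone were PCNA, the sliding clamp of the replication fork, with -0.31 (SE 0.07), and GINS1, with -0.32 (SE 0.07). MCM3 differed by -0.30 and CDC45 by -0.21. The median on the fructose arrays was -0.20, -0.08 and -0.26, and without fructose replicate 2 the list stood at -0.23. Cell division genes fell by a median of 0.06 (24 genes, 20 lower, adjusted p = 4.76e-04 and 0.43 with an estimated correlation), with none past the threshold when adjusted over the list alone. TTK differed by -0.37, CENPE by -0.29, KIF11 by -0.22 and NUSAP1 by -0.20. MKI67, a common marker of cycling cells, differed by -0.02 (95% interval -0.16 to 0.13). On the fructose arrays the median of the cell division list was -0.05, -0.01 and -0.14, so that replicate 2 lay within the range of the glucose arrays (-0.01 to 0.01), and it was -0.02 without fructose replicate 3 and -0.09 without fructose replicate 2. Histone genes fell as a group (10 genes, 9 lower, median -0.11, adjusted p = 0.011 and 0.36 with an estimated correlation), with H2BC4 at -0.21 and H1-2 at -0.14 and no member past the threshold when adjusted over the list alone. Without glucose replicate 3 their adjusted p was 0.055 and their median -0.06. Ribosome biogenesis and MYC targets fell by a median of 0.05 (19 genes, 15 lower, adjusted p = 0.024 and 0.35 with an estimated correlation), and none passed when adjusted over the list alone. NOP58 and WDR43 differed by -0.18 each and NOLC1 by -0.15, while MYC, the oncogene that drives this list in many cells, was higher by 0.39. Its intensity was 1153, 896 and 1161 on the fructose arrays and 778, 882 and 780 on the glucose arrays, so fructose replicate 2 lay near glucose. The call of the ribosome biogenesis list was lost without glucose replicate 3 and without fructose replicate 3, where the largest adjusted p was 0.076, and after repeated quantile normalization (0.066).

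Targets of the hypoxia factor HIF fell by a median of 0.05 (19 genes, 14 lower, adjusted p = 0.024 and 0.35 with an estimated correlation). Adjusted over the list alone, 2 fell and 1 rose. P4HA1, a collagen prolyl hydroxylase subunit, differed by -0.38, NDRG1 by -0.26 and PDK1 by -0.25, and the collagen cross-linking enzyme LOX was higher by 0.41. The call was lost without glucose replicate 3 and without fructose replicate 3 (largest adjusted p 0.054) and among bright probe sets alone (0.053), and the median was -0.09 without fructose replicate 2. The 4091 probe sets taken as controls had a median difference of -0.06, with 8.80% at an unadjusted p under 0.05 and 0 called, which is about the size of the medians of the HIF, ribosome biogenesis and cell division lists. Mean log2 values of these controls were 6.18, 6.19 and 6.21 on the fructose arrays and 6.26, 6.31 and 6.26 on the glucose arrays. Mesenchymal and extracellular matrix genes rose by a median of 0.05 (26 genes, 20 higher, adjusted p = 0.047 and 0.41 with an estimated correlation), with 2 up when adjusted over the list alone. SNAI2, a repressor of epithelial genes, was higher by 0.46 (SE 0.07), COL6A1 by 0.37 and TGFB1 and ZEB2 by 0.27 each. Their call was lost when any array other than fructose replicate 3 was left out (largest adjusted p 0.12) and after centring each array on its median (0.058), and the median was 0.11 without fructose replicate 3. Epithelial genes were not shifted as a list (18 genes, 9 higher and 9 lower, adjusted p = 0.091), although the list passed without glucose replicate 3 (0.025). Its median of 0.01 had the opposite sign to its test, but the median was negative in 5 of the 6 fits that left out an array. Adjusted over the list alone, 3 fell, the keratins KRT7 (-0.47) and KRT8 (-0.27) and the adhesion molecule EPCAM (-0.47), whereas KRT19 was higher by 0.12.

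Markers of other cell types did not shift as lists. The adjusted p was 0.33 for luminal breast cells (12 genes), 0.21 for leukocytes (9 genes) and 0.71 for fibroblasts (10 genes). Of the luminal markers, 2 rose and 1 fell when adjusted over the list alone, and MLPH, a melanosome transport protein, was higher by 0.39. Among the leukocyte markers LAPTM5, a lysosomal membrane protein, was higher by 0.66 and passed when adjusted over the list alone, and the common leukocyte antigen PTPRC differed by 0.06. By fry the leukocyte list had an adjusted p of 0.012. Some markers also belong to other lists here, KRT8, KRT18 and XBP1 among the luminal markers and COL1A1, COL1A2 and COL3A1 among those of fibroblasts.

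**Figure D3:**
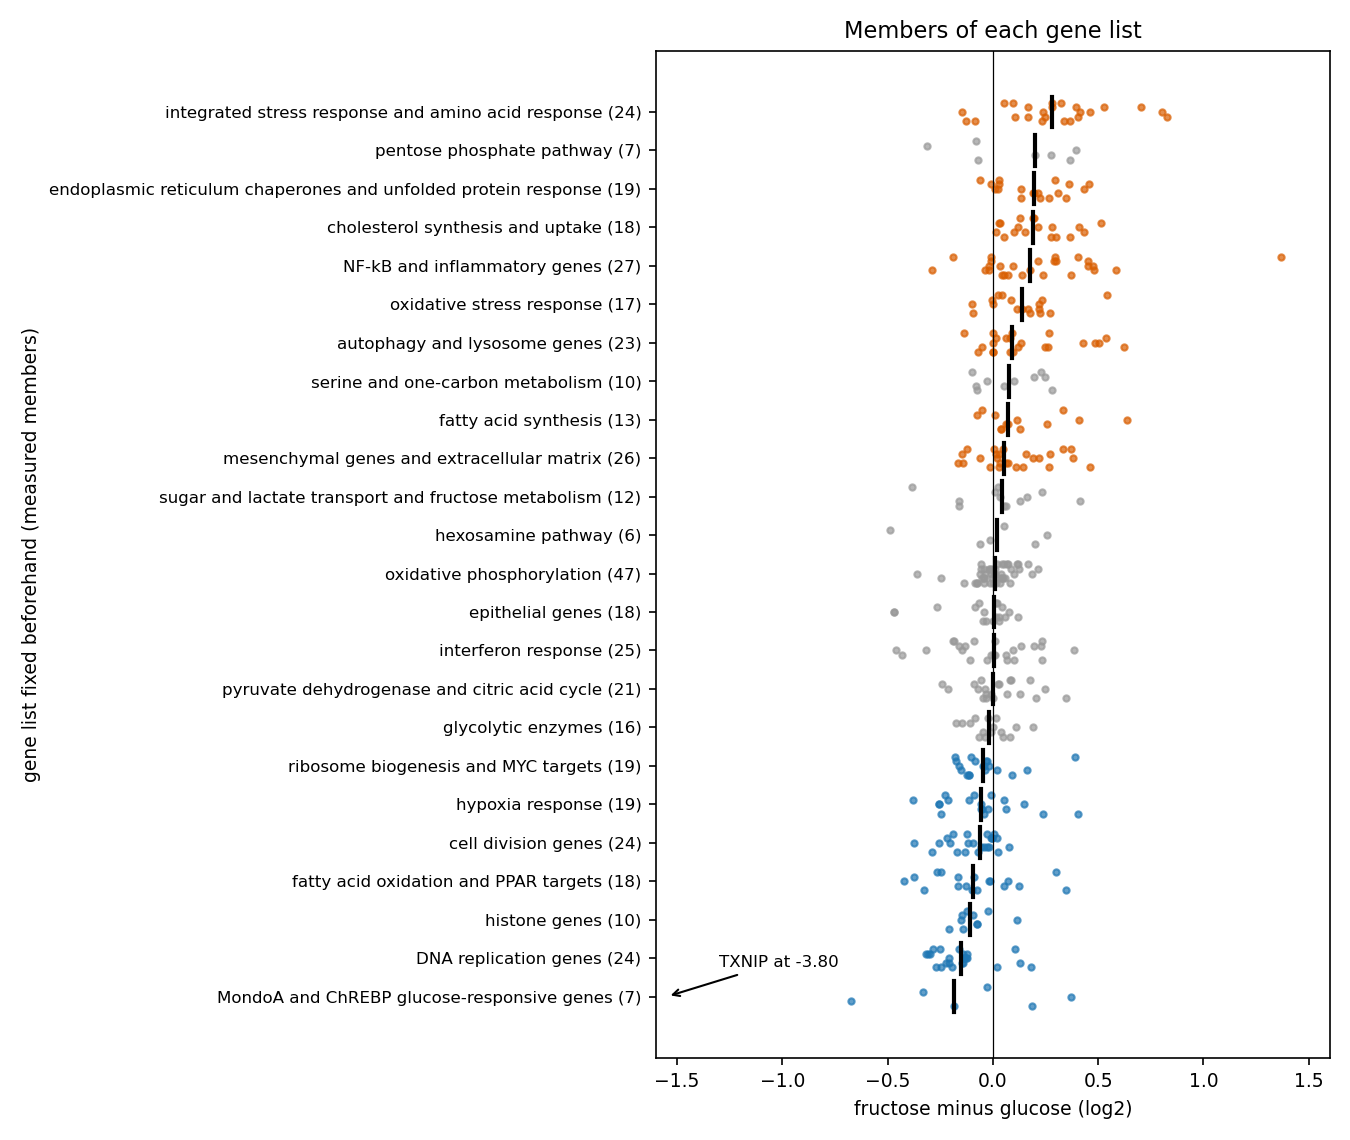
Log2 difference between fructose and glucose for each measured member of the 24 lists, as a point, with the list median as a black bar. Orange lists rose, blue lists fell and grey lists did not pass, and TXNIP lies beyond the left edge at -3.80.

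Over all probe sets, 1 gene passed the limma test, and the smallest adjusted p among the rest was 0.064. Without adjustment, 3694 probe sets had a p under 0.05, or 13.1% of those tested, where 1412 would be expected by chance, and at this level 1569 genes were higher and 1056 lower. The probe sets taken as controls had 8.80% at this p. The median difference over all tested probe sets was 0.02, and centring each array on its median left 2206 such genes of 2625. All 3 fructose arrays lay above all 3 glucose arrays for 2396 of the 18404 genes and below them for 1840, where chance gives 10% for both directions together. At least 2-fold differences were seen in 7 genes, chosen after their values were seen. These were TXNIP, the small nucleolar RNAs SNORD14E (-1.16) and SNORD28 (-1.01) and the histone H2BC1 (-1.03) on the lower side, and MMP1, the protease TMPRSS11E (1.33) and the kinase RPS6KA2 (1.08) on the higher side. TXNIP apart, their adjusted p values were between 0.070 and 0.26. The gap junction gene GJA1 (-0.87) and CYP1B1 (0.98), which oxidises steroids and xenobiotics, both picked after their values were seen, had an adjusted p of 0.064. The number of genes past the threshold moved with the setting. It was 388 with an intensity trend and robust variances together, 277 among bright probe sets, 35 with 1 probe set per gene and 0 by a test without shared variances, in which TXNIP itself had an adjusted p of 0.088.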

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

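The control probe set and TXNIP alternatives were chosen after seeing the data; the others were planned. TXNIP kept its direction under all 16 alternatives, with log2 differences from -3.89 to -3.72. It kept its call under 15 of them, with limma adjusted p values from 1.54e-08 to 0.00199. The exception was the unmoderated test, where its adjusted p was 0.0878. That test has fewer degrees of freedom per gene and called 0 genes at any size, with 2751 genes at an unadjusted p under 0.05. The count of 1 gene became 277 (158 higher, 119 lower) among bright probe sets, 388 (213 higher, 175 lower) with an intensity trend and robust variances, and 35 (18 higher, 17 lower) with either the mean of a gene's probe sets or representative probe sets alone. The 2-fold count of 1 became 6, 6, 5 and 5 in these settings. All but the trend adjusted over fewer probe sets; the cause was not tested further. Between the 277 and the 388 genes 245 were shared, and 33 were shared by all 4 sets. Leaving out each array gave 1 gene, 1 gene at least 2-fold and 12 to 14 lists. Both kinds of normalization, array weights and control probe sets kept gave 1 gene. The fit with a replicate block gave 1 gene, 1 gene at least 2-fold and 14 lists, without the mesenchymal list (adjusted p = 0.0514). The numbers are not known to pair the arrays. Deviations of same-numbered arrays correlated at -0.026, -0.021 and -0.054, and no array correlated best with its own number. Of 15 lists, 0 passed with an estimated correlation, where 1 list had an unadjusted p under 0.05, and 8 passed with fry (5 up, 3 down); that camera test refers to 4 residual degrees of freedom, which alone raises its p values, and the estimate is imprecise. For fry the cause was not tested. With TXNIP left out of its list, 13 lists passed, without the MondoA and mesenchymal lists. Over the other settings 14 or 15 lists passed, and 9 lists kept their call in every leave-one-out fit and in 7 other settings. Of 384 list values 343 kept their side of the threshold, 40 lost the call and 1 gained it. Of 1769 gene values 103 gained a call, 1 lost it, and 4 changed sign without being called. List medians with representative probe sets alone are those given, and the unmoderated test does not apply to lists. Dim probe sets limit what can be read of genes such as SLC2A5 and KHK, since RMA values near the background understate differences.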

Other observations

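The tests of small nuclear RNAs, of fructose replicate 2, and of lists inside the random range were chosen only after the result was seen, as were the families of genes and the class of small nucleolar RNAs. The estimated correlation was a setting fixed beforehand, and its use as a test of an explanation was chosen after the result was seen.

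Genes that share a symbol stem were grouped where at least 8 of them were bright, which gave 187 families, and 7 passed with camera. None did with an estimated correlation, where the smallest adjusted p was 0.41. Nucleoporins, the proteins of the nuclear pore, fell by a median of 0.14 with 18 of 20 lower (adjusted p = 6.74e-05, and 0.97 with an estimated correlation). NUP54 differed by -0.36, NUP155 by -0.26 and NUP205 by -0.25. The MCM genes, most of them parts of the replicative helicase, fell with 10 of 11 lower and a median of -0.19 (adjusted p = 8.52e-04, and 0.97 with an estimated correlation), and so did the RAD genes, many of them for DNA repair, with 10 of 14 lower (0.0062 and 0.97). A family of 46 genes, nearly all of them histones, had 41 lower and a median of -0.14 (2.64e-09 and 0.97). MCM2, MCM3, MCM4, MCM5, MCM6, MCM7 and MCM10 are also in the DNA replication list tested above. The histone family likewise shares members with the histone list, among them H1-2 and H2BC4. For these genes the family results are not separate evidence. Metallothioneins, which bind zinc and copper, rose with 13 of 13 higher and a median of 0.14 (0.029 and 0.97), led by MT1X at 0.39, but these genes are near-identical in sequence and uncertain as single genes. DOCK genes, guanine nucleotide exchange factors of RAC and CDC42, rose with 8 of 9 higher and a median of 0.16 (0.015 and 0.97), with DOCK4 at 0.50 and DOCK9 at 0.49. Single members did not pass over all probe sets. Of the 7 families, the DOCK genes and the C/D box small nucleolar RNAs described below also passed by fry (adjusted p = 0.041 each). By fry the adjusted p was 0.18 for nucleoporins, 0.20 for MCM genes, 0.13 for RAD genes, 0.16 for the histone family and 0.18 for metallothioneins.

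In all 4 alternatives that called more genes, 33 genes passed, 16 higher and 17 lower in fructose, and they were chosen after their values were seen. These settings use the same arrays and are not separate tests. Of the 35 genes called with representative probe sets alone, 34 passed with the trend and 33 among bright probe sets. On the higher side they held ALDH2, which clears acetaldehyde (0.65), the lysosomal protease CTSS (0.86), the glucokinase regulator GCKR (0.78), the phosphatase DUSP10 (0.75), the cyclin CCNA1 (0.71) and the adhesion molecules CDH11 (0.58) and CD82 (0.58). CTSS and GCKR were dim in glucose, with mean log2 values of 4.64 and 4.75. On the lower side, besides TXNIP and GJA1, stood 6 C/D box small nucleolar RNAs, the histones H2BC1 (-1.03) and H2AC1, the autophagy protease ATG4C (-0.51), the sarcoglycan SGCE (-0.57) and OGA (-0.49).

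Bright C/D box small nucleolar RNAs, which guide ribosomal RNA methylation, were lower in fructose, with 41 of 50 lower and a median of -0.27 (95% bootstrap interval -0.41 to -0.18). The fructose arrays read -0.26, -0.25 and -0.33, and camera gave an adjusted p of 1.78e-16, and 0.41 with an estimated correlation. All bootstrap intervals given here resample genes on the same arrays, so they do not measure the spread between cultures. A trend with brightness is argued against, since 0% of 10000 random lists matched on mean expression had as low a median. So is a loss of all small RNAs in the fructose preparations. There, 13 small nuclear and 7SK or 7SL type RNAs had a median of 0.20 (0.06 to 0.31) and 29 microRNA precursors 0.0071 (-0.065 to 0.063). The 9 small Cajal body RNAs, at 0.13 (-0.17 to 0.35), were too variable to decide. These values do not test a loss of only some small RNAs, such as one that depends on their length. For the 20 of these RNAs that lie within 14 measured hosts, lower host transcripts are argued against as a set. The median of the hosts was 0.0026 (-0.039 to 0.038) while that of their small nucleolar RNAs was -0.28. However, RPL17, host of SNORD58A (-0.50), itself differed by -0.38 (SE 0.13). Hosts were not tested for the remaining RNAs. Those include all C/D box RNAs among the genes shared by the alternatives above, such as SNORD28 and SNORD74. A loss of small nucleolar RNAs of both box types stays open, as the 36 H/ACA RNAs had a median of -0.056 (-0.14 to 0.01), so a change in processing or stability under fructose may be considered only as an untested hypothesis beside it.

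The ATF4 and unfolded protein response lists were higher on fructose replicates 1 and 3 and not on replicate 2, where 39 of 43 genes lay below both other fructose arrays and the median was -0.03 against 0.36. A glucose culture labelled as fructose replicate 2 is argued against, since TXNIP there lay at -3.80 relative to glucose. For the 41 genes of the cholesterol and lysosome lists, picked after the result was seen, the ratio of replicate 2 to replicates 1 and 3 was 1.33 (0.78 to 2.05). That interval resamples genes, and replicate 2 is a single culture, so it does not measure the spread between cultures. The medians of these lists on replicate 2 (0.21 and 0.15) already lay above those on replicate 3 (0.13 and 0.05). The ratio therefore describes these lists and is no separate test. Replicate 2 also lay nearest to glucose among the fructose arrays for NF-kB, NRF2 targets, DNA replication, cell division and fatty acid oxidation. It did not for the remaining shifted lists. A weaker response of replicate 2 in many lists, though not in every list, therefore stays open. A state of the cultures that could differ between separately adapted batches stays open as well. The labels state the same approximate confluency (70%) and time after feeding (24 hours) for all 6 arrays and give no measurement per culture that would test it.

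The 15 shifted lists were weighed against brightness, correlation between genes and other splits of the arrays. Of these, 10 had a median outside the central 95% of 10000 random lists matched on mean expression, which argues against a trend with brightness for them, and 5 lay inside it, namely HIF targets, fatty acid synthesis, cell division, ribosome biogenesis with MYC targets and mesenchymal genes, for which such a trend cannot be told apart from a shift. Correlation between the genes of a list stays open, since the smallest adjusted p was 0.35 with an estimated correlation. That test also has only 4 residual degrees of freedom. The estimates were 0.81 for the unfolded protein response, 0.72 for ATF4, 0.62 for DNA replication and 0.40 for cell division, far above the preset 0.01. For HIF targets and ribosome biogenesis they were -0.0060 and -0.034, below the preset 0.01, so a larger correlation was not what ended those calls. The remaining shifted lists had estimates between 0.031 and 0.18. In 1 of the 10 splits, the real split, as many lists passed (15, highest other 8), and likewise as many genes (1 against 0, also at 2-fold), as many probe sets at an unadjusted p under 0.05 (3694 against 1737), and as many genes among bright probe sets (277 against 0), with an intensity trend and robust variances (388 against 0) and among representative probe sets (35 against 0). With 10 splits a share under 0.05 cannot be reached.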
